A study of Macaca mulatta with 2 samples.

How the data were processed

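Total RNA of peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes separated from blood) of the rhesus macaque was sequenced as 2 libraries, titled LongInsert and Regular. Per the labels, a single RNA sample served for both, so the design holds no biological contrast and compares library preparations and instruments. There was 1 library per group, no replicate of either preparation, and therefore no estimate of error for any difference between them. Per the labels' protocols, RNA was isolated with a miRNeasy kit, and the library for one run followed a standard Illumina protocol. For the other run, on a MiSeq, cDNA was made with a kit given as SMRT, turned into a library with Nextera (a transposase that cuts and tags cDNA) and selected for size on a gel. The same protocol text is attached to both libraries. The series text gives paired reads of 300 nt for the MiSeq and 75 nt for the second instrument.

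Which title belongs to which run could not be settled. The size selection described for the MiSeq library goes with the title LongInsert, whereas the instrument named with the table deposited under that title is a HiSeq, and the MiSeq is named with the table titled Regular. The second instrument is a GAIIx in the series text, a NextSeq in the protocol and a HiSeq in the name of the table. Groups were taken from the titles alone, no read length or instrument was assigned to either library, and every direction below refers to the title only.

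The authors deposited 1 table per library with a TPM value (an abundance scaled for transcript length and library total) for each transcript, per the file headers. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic and STAR without giving their order or role, and the series title names Isolator, a program that estimates isoform abundance. The genome build, the annotation release and the settings of the quantification are not given in the sources used here. Both tables list the same 9267 transcripts of 7904 genes, with Ensembl macaque identifiers. The listed values sum to 130234 TPM in LongInsert and 152883 TPM in Regular, or 13.0% and 15.3% of the 1000000 TPM that a complete library would hold. The rest of each library was not analysed here. No listed value was exactly 0 in either library. TPM keeps no record of read number, so the depth of both libraries is unknown, and no counting interval or detection floor is given for any abundance.

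Gene symbols came from a table of Ensembl identifiers, in which 724 of the 7904 genes had a match, to 712 distinct symbols. The other 7180 genes are used in counts by identifier only. A symbol can belong to a near-identical copy of the gene it names, and reads of ribosomal protein genes can be shared among copies, so their values are uncertain. No coordinates, transcript lengths or GC contents were used, since no genome or transcript sequence of the build was at hand, and the planned comparison with transcript length and GC content was not run.

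Abundances were compared as log2((LongInsert + 1)/(Regular + 1)), with a pseudocount of 1 TPM, which understates the change of low genes. Gene values are sums over a gene's listed transcripts. With 1 library per group there was no test, and genes and transcripts were set apart by a rule of size, a difference of 2-fold or more among features with a mean of 1 TPM or more over both libraries. Agreement across genes or transcripts was described with Pearson's r on log2(TPM + 1) and Spearman's rho on TPM. Genes are not independent replicates, so no p-value is given. Exact (Clopper-Pearson) 95% intervals of shares of genes describe the number of genes counted, not error between libraries. Isoform usage is the share of a gene's TPM taken by the transcript that leads in LongInsert, in genes with 2 or more transcripts and a mean of 5 TPM or more.

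Before the data were examined, 22 gene lists were fixed, among them lists for blood cell types, ribosomal proteins, the respiratory chain, antigen presentation, interferon response, housekeeping, the spliceosome and very long mRNAs. A list with at least 5 members at a mean of 1 TPM or more was to be described by its median and the percentile of that median among 10000 random lists of other genes of the same size, matched on deciles of mean TPM. Members of shorter lists are given as values. The genes named were fixed by rule as the 10 with the highest mean TPM, the 12 highest and 12 lowest log2 ratios among genes with a mean of 10 TPM or more, the 4 most abundant members of each list, and the 6 genes with a mean of 20 TPM or more and the largest difference in isoform usage, all among genes with a symbol. A few genes that this rule takes are not reported here by name, although they are included in the counts. Alternatives tried were other pseudocounts (0.1 and 5 TPM), other minimum abundances, ratios centred on the median of genes with a mean of 10 TPM or more, TPM rescaled without the 10 most abundant genes, and other limits for isoform genes.

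The functions were tested on simulated data made from the mean TPM of the 7904 genes in the comparison of LongInsert with Regular. A 4-fold change was given to 200 genes with a mean of 10 TPM or more. Over noise with an SD of 0.2 on the log2 scale, 100.0% were recovered in either direction. In a simulation of 105 genes without noise, all 30 swapped isoform pairs were found. These runs check the code only, since the log2 ratios of the real libraries had SDs from 1.82 to 2.58 by abundance. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.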

Results

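Transcript abundance in rhesus macaque PBMC was measured from a single RNA sample in 2 libraries, titled LongInsert and Regular. Each library was represented by TPM values for 9267 transcripts of 7904 genes. In LongInsert, 1322 genes reached 1 TPM, 656 reached 10 TPM and 162 reached 100 TPM. In Regular, 1015 genes reached 1 TPM, 498 reached 10 TPM and 142 reached 100 TPM. Of the genes at 1 TPM or more in at least 1 library, 833 reached that level in both, 489 in LongInsert alone and 182 in Regular alone. The 10 most abundant listed genes of each library made up 28.7% of the listed TPM in LongInsert and 51.5% in Regular. Among the listed genes, which hold only part of each library, the most abundant in both was ENSMMUG00000028701, for which no symbol was at hand, at 6662 TPM in LongInsert and 33901 TPM in Regular.

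The most abundant listed genes with a symbol encoded ribosomal proteins and ubiquitin. RPL10, a protein of the large ribosomal subunit, had 3295 TPM in LongInsert and 9959 TPM in Regular, and the abundant gene with the symbol RPSA (ENSMMUG00000022965), a protein of the small subunit, had 2532 and 7539 TPM. The polyubiquitin gene UBB, at 1277 TPM in LongInsert and 4084 TPM in Regular, was also lower in LongInsert. RPL7 and RPL19 were close in both libraries, with 2409 and 2530 TPM for RPL7 and 1572 and 1586 TPM for RPL19. RPL9 had 3548 TPM in LongInsert and 2402 TPM in Regular, RPL6 had 2914 and 1385 TPM, and RPL15 had 748 and 2247 TPM. The more abundant of the pair of genes with the symbol RPS24 (ENSMMUG00000030562) had 2692 TPM in LongInsert and 840 TPM in Regular.

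The design asks how closely abundances agree when the same RNA is prepared and sequenced in different ways. Across all 9267 transcripts, Pearson's r of log2(TPM + 1) was 0.817 and Spearman's rho was 0.563. Summing transcripts per gene gave an r of 0.831 and a rho of 0.507 over 7904 genes. Among the 724 genes with a symbol, r was 0.889 and rho was 0.844. Most listed genes were near 0 in both libraries, and over the 1310 genes with a mean of 1 TPM or more r was 0.633 and rho was 0.514. Over the 365 of these with a symbol, r was 0.794 and rho was 0.764. Of the 685 genes with a mean from 1 to 10 TPM, 24.5% lay within 2-fold (95% interval over genes, 21.3 to 27.9%), with a median log2 ratio of 1.45 in favour of LongInsert. Of the 472 genes from 10 to 100 TPM, 30.9% lay within 2-fold (26.8 to 35.3%), and the median was 0.90. From 100 to 1000 TPM the share was 45.6% of 125 genes (36.7 to 54.7%) with a median of 0.07, and above 1000 TPM it was 46.4% of 28 genes (27.5 to 66.1%) with a median of 0.02. The SD of the log2 ratios was 1.82 from 1 to 10 TPM, 2.58 from 10 to 100 TPM, 2.43 from 100 to 1000 TPM and 2.06 above 1000 TPM. The pseudocount limits the size of ratios at low abundance, so the SD of the lowest group cannot be compared with the others.

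**Figure D1:**
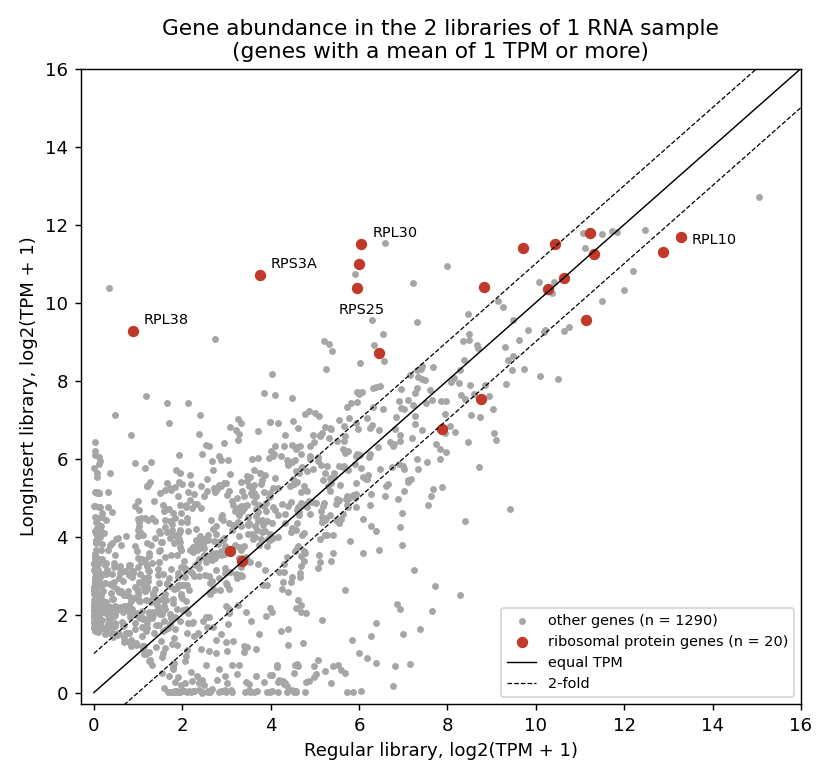
Abundance of the 1310 genes with a mean of 1 TPM or more, as log2(TPM + 1), in the Regular library (horizontal axis) and the LongInsert library (vertical axis). Each point is 1 gene, red points are the 20 ribosomal protein genes, the solid line marks equal TPM and the dashed lines mark 2-fold differences. RPL38, RPS3A, RPL30 and RPS25 lie far above the upper dashed line, RPL10 lies below the lower one, and rows of genes along both axes were near 0 TPM in a single library.

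Among the 1310 genes with a mean of 1 TPM or more, 666 were at least 2-fold higher in LongInsert, 260 were at least 2-fold lower, and 384 (29.3%) were within 2-fold. The median log2 ratio of the 625 genes with a mean of 10 TPM or more was 0.59, and with ratios centred on it 505 genes were higher and 334 lower, so that higher genes made up 60.2% of those that differed in place of 71.9%. Among the 365 genes with a symbol, 196 were higher and 35 lower, or 133 and 53 after centring. Among the 945 without a symbol, 470 were higher and 225 lower, or 372 and 281 after centring. Of 1500 transcripts with a mean of 1 TPM or more, 777 were higher and 308 lower in LongInsert, or 599 and 399 after centring on a median of 0.59. No difference has a replicate check, so none could be set against a spread between libraries of the same kind.

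Among genes with a symbol and a mean of 10 TPM or more, the 12 with the highest ratios in favour of LongInsert included 5 ribosomal protein genes. RPL38 had 618 TPM in LongInsert and 0.837 TPM in Regular, RPS3A had 1665 and 12.5 TPM, RPL30 had 2902 and 65.4 TPM, RPL39 had 2032 and 63.4 TPM, and RPS25 had 1315 and 60.6 TPM. CMC1, a mitochondrial protein needed for cytochrome c oxidase, had 64.5 TPM in LongInsert and 0.0756 TPM in Regular. TMEM258, a subunit of the oligosaccharyltransferase complex, had 57.5 and 0.0768 TPM, and PSMD13, a subunit of the proteasome's regulatory particle, had 45.3 and 0.0551 TPM. The tyrosine phosphatase gene PTP4A1 had 169 TPM in LongInsert and 2.16 TPM in Regular, and DEK, a chromatin protein, had 95.5 and 0.799 TPM. SETD1B, a histone H3 lysine methyltransferase, had 26.4 TPM in LongInsert and 0.0036 TPM in Regular, and SMG1, a kinase of nonsense-mediated mRNA decay, had 137 and 4.31 TPM. The log2 ratios of these 12 genes ran from 4.42 for RPS25 to 8.40 for RPL38.

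Among the same genes with a symbol, the 12 lowest ratios ran from -4.59 for DGCR6L to -1.63 for OTUB1 on the log2 scale. DGCR6L had 3.79 TPM in LongInsert and 114 TPM in Regular. SULT1A3, a sulfotransferase, had 5.19 and 50.2 TPM, and PSMD9, a chaperone of proteasome assembly, had 11.7 and 86.8 TPM. TECR, an enzyme of very long chain fatty acid synthesis, had 18.1 TPM in LongInsert and 120 TPM in Regular, and ACOT7, an acyl-CoA thioesterase, had 18.2 and 76.0 TPM. The zinc finger repressor ZGPAT had 32.0 and 197 TPM, the ribosome biogenesis factor PPAN had 8.08 and 32.6 TPM, and the actin-binding protein CNN2 had 62.5 and 228 TPM. NDUFA9, of respiratory complex I, had 41.4 TPM in LongInsert and 137 TPM in Regular, the methyltransferase gene EEF2KMT had 6.08 and 21.1 TPM, and the deubiquitinase gene OTUB1 had 59.2 and 185 TPM. UBB, named above among the most abundant genes, was also in this group, with a log2 ratio of -1.68. Genes without a symbol went further in both directions. Of these, ENSMMUG00000003738 had 1333 TPM in LongInsert and 0.27 TPM in Regular, a log2 ratio of 10.04, and ENSMMUG00000023048 had 0.126 and 109 TPM, a log2 ratio of -6.61. Both fall outside the rule for named genes and were chosen after their values were seen.

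Only 1 of the 22 fixed gene lists, that of cytosolic ribosomal proteins, had enough members for a summary. Its 20 genes with a mean of 1 TPM or more, with 18 distinct symbols, split into 9 that were at least 2-fold higher in LongInsert, 5 at least 2-fold lower and 6 within 2-fold. The lower genes included RPL10, RPL15, RPSA (ENSMMUG00000022965) and RPS27A, with log2 ratios from -1.60 to -1.11. RPL24, with 1299 TPM in LongInsert and 1246 TPM in Regular, was within 2-fold. The median log2 ratio of the list was 0.56, at percentile 92.3 of random lists matched on abundance, whose central 95% ran from -0.82 to 0.71. Over the 18 members with a mean of 10 TPM or more the median was 0.82, at percentile 99.9 and so outside the central 95% of its random lists. That minimum left out only members with means from 9.28 to 9.39 TPM, so the percentile was sensitive to it. Of the 625 genes at that minimum, 221 had a symbol. Genes without a symbol were lower in LongInsert more often, at 23.8% against 9.59% with a mean of 1 TPM or more. Random lists of genes with a symbol only were not drawn here. Before centring, the mean of the 20 genes was 1.54. After centring, which subtracts 0.59 from every gene, their median was -0.03, so its sign depended on the scaling. The list stayed at percentile 92.3, since its random lists, with a median of 0.08 before centring, shift with it. Both genes with the symbol RPS24 were higher in LongInsert, the less abundant one with 415 and 86.9 TPM, whereas the less abundant RPSA gene (ENSMMUG00000004941) was near equal at 9.39 and 9.18 TPM.

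**Figure D2:**
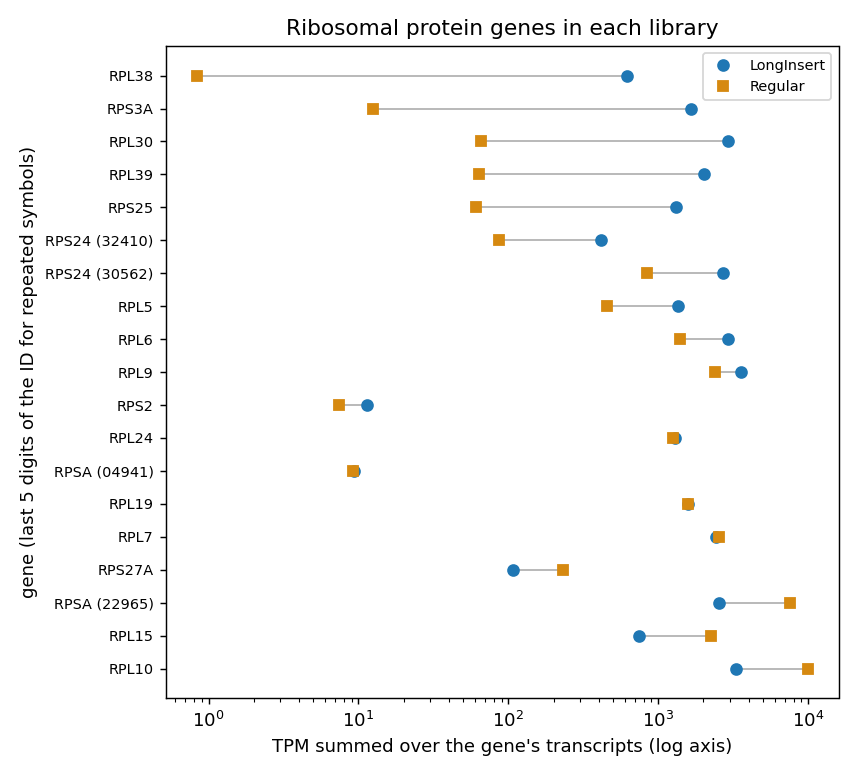
TPM of 19 of the ribosomal protein genes in LongInsert (blue circles) and Regular (orange squares), on a log axis, 1 gene per line and ordered by their log2 ratio. The top line is RPL38 (618 and 0.837 TPM) and the bottom line is RPL10 (3295 and 9959 TPM), and each value is from 1 library, without an error.

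The other lists had at most 4 members at a mean of 1 TPM or more and are given as values. Of the nuclear-encoded respiratory chain, NDUFB8 had 101 TPM in LongInsert and 288 TPM in Regular, and NDUFA9 was lower in LongInsert as given above. ATP5F1B, of the ATP synthase, had 242 and 307 TPM and SDHD, of succinate dehydrogenase, had 67.0 and 63.5 TPM, both within 2-fold. All 3 listed members of the very long mRNA list were higher in LongInsert by 2-fold or more, also after centring. So were 53.7% of the 365 genes with a symbol and a mean of 1 TPM or more, or 36.4% after centring. With so few members, the list cannot show an effect of length. MACF1, a cytoskeletal crosslinker, had 200 and 63.0 TPM. MDN1, a ribosome assembly ATPase, had 36.7 and 5.56 TPM, and VPS13D, a lipid transfer protein, had 25.2 and 2.24 TPM. Of the spliceosome, the splicing factor gene U2AF2 had 104 TPM in LongInsert and 12.1 TPM in Regular, and SNRPD2 had 10.5 and 4.60 TPM, a log2 ratio of 1.03 that was 0.44 after centring. Of the housekeeping list, POLR2A, the largest subunit of RNA polymerase II, had 67.6 and 2.82 TPM. The proteasome subunit gene PSMA1 had 118 and 152 TPM, the interferon-induced gene USP18 had 9.86 and 5.66 TPM and the platelet integrin gene ITGB3 had 3.29 and 1.77 TPM. The red cell list was represented by the haemoglobin gene HBA1 alone, at 0.0093 TPM in LongInsert and 0.0035 TPM in Regular, and the list of small structured RNAs by 10 genes with the symbol Metazoa_SRP, of which the highest (ENSMMUG00000012342) had 0.767 and 0.0409 TPM. The other 12 lists, those of T, B, NK and cytotoxic, monocyte, dendritic and neutrophil markers among them, had no gene with a matching symbol among the genes analysed, so the cell types of the sample could not be compared.

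The comparison of isoforms asked whether both libraries assigned a gene's abundance to the same transcript. Of 194 genes with 2 or more transcripts and a mean of 5 TPM or more, 140 had the same leading transcript in both libraries, or 72.2% (95% interval over genes, 65.3 to 78.3%), and 54 had different ones. Only 2 transcripts were listed for 105 of the 194, where a shared leader is more likely without any agreement. The usage of the transcript that led in LongInsert differed by a median of 11.7 percentage points, by under 10 points in 88 genes and by 50 points or more in 20 genes. It was lower in Regular in 117 genes, a lean that picking the leader in LongInsert favours. Picking the leader in Regular could give another set. The 6 named genes all had a different leading transcript in each library, which their choice by the largest difference in usage makes likely. In PPAN, ENSMMUT00000024198 took 99.6% of the gene's TPM in LongInsert and 1.44% in Regular, where ENSMMUT00000024197 took 98.6%. MOBKL1B, with near-equal totals of 216 TPM in LongInsert and 194 TPM in Regular, changed from 85.0 to 21.7% for ENSMMUT00000043456. In NPM1, a nucleolar chaperone, ENSMMUT00000022164 took 259 of the gene's 259 TPM in LongInsert and 81.5 of its 179 TPM (45.6%) in Regular. There ENSMMUT00000022165 led with 97.1 TPM, against 0.0605 TPM in LongInsert. The usage of the LongInsert leader was 94.6% and 32.0% in BRD10, 73.3% and 20.8% in the nuclear pore gene POM121C, and 75.5% and 23.3% in SULT1A3. Their totals were 38.8 TPM in LongInsert and 6.17 TPM in Regular for BRD10, and 46.9 and 13.5 TPM for POM121C. SULT1A3 had 5.19 and 50.2 TPM. Shares of so low a total rest on a few TPM, and depth is unknown.

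**Figure D3:**
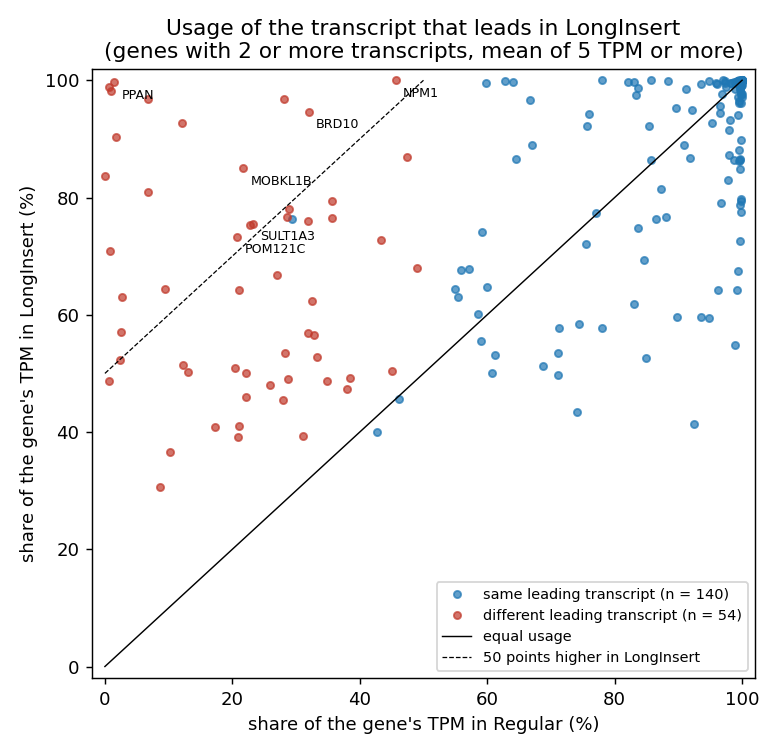
Usage of the transcript that leads in LongInsert, as its share of the gene's TPM (%), in Regular (horizontal axis) and LongInsert (vertical axis), for 194 genes with 2 or more transcripts and a mean of 5 TPM or more. Blue points are the 140 genes with the same leading transcript in both libraries and red points the 54 with different ones, and PPAN lies at the upper left with 1.44% in Regular and 99.6% in LongInsert.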

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

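With 1 library per group, no replicate could be left out and no test could lose or gain a call. Of 44 summary values recomputed under the alternatives, 28 stayed within their range. That range was 1.5 times for counts of genes, and a 95% bootstrap or binomial interval over genes otherwise. Counts were compared without regard to the number of features tested. A count could therefore leave its range only because a filter changed that number, and the tally does not measure dependence on processing alone. The ribosomal protein median after centring counted as within its range although its sign changed. The 24 genes with the highest and lowest ratios kept their direction and a 2-fold difference in all 96 recomputed values. They were picked for extreme ratios, which these alternatives could hardly reverse, so that result is no check on them. A minimum mean of 1 TPM lowered the correlation of transcripts to an r of 0.604 and a rho of 0.470. For genes it lowered r to 0.633, whereas rho was 0.514, against 0.507 without the minimum. It left out the many features near 0 in both libraries and kept those abundant in a single one. With a pseudocount of 0.1 TPM, r was 0.795 for transcripts and 0.807 for genes. A pseudocount of 5 TPM left 420 genes and 487 transcripts higher in LongInsert. A minimum mean of 10 TPM, which tests fewer features, left 266 genes higher and 143 lower, and 299 transcripts higher and 160 lower. Restricting the counts to genes with a symbol, an alternative chosen after seeing the data, left 196 higher and 35 lower. A difference of 50 points in isoform usage was seen in 37 genes at a minimum mean of 1 TPM and in 9 at 20 TPM, as more or fewer genes were included, and the share of genes with the same leading transcript was 80.8% where that transcript took at least 60% of the gene in LongInsert. The ribosomal protein median ran from -0.03 after centring to 0.82 at a minimum mean of 10 TPM. It stood at percentile 92.3 of the random lists after centring, as before it, and at percentile 99.9 at that minimum. At either minimum most genes open to the random lists had no symbol, unlike the members. The planned matching of random lists on transcript length, and the comparison with length and GC content, were not run, since no transcript sequences were at hand. Depth is unknown, so a low value in either library cannot be told from too few reads.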

Other observations

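All tests in this part were chosen after the results they bear on had been seen, and no biological explanation was tested, since both libraries come from a single RNA sample. Genes known from white blood cells were among those with a symbol although none was in the fixed lists. A set of 16 such genes, chosen after their values were seen, held 5 that were at least 2-fold higher in LongInsert, 1 that was lower and 10 within 2-fold, or 3, 4 and 9 after centring. LSP1, an actin-binding protein of lymphocytes, had 396 TPM in LongInsert and 719 TPM in Regular. BIN2, a membrane-curving protein of leukocytes, had 580 and 355 TPM. The adhesion molecule gene PECAM1 had 282 and 142 TPM, MYO1F, an unconventional myosin, had 176 and 118 TPM, and ARHGAP30 had 328 and 172 TPM. Differences were larger for DOCK10, a guanine nucleotide exchange factor (122 and 14.9 TPM), the C-type lectin gene CD302 (18.9 and 2.42 TPM) and the integrin gene ITGAE (13.3 and 2.5 TPM). CORO7, a coronin, was the 1 lower gene, at 31.8 and 94.7 TPM. The other genes of the set were TNFSF12, CCDC88B, EVI2A, FCGR1A, FCRL5, SIRPA and TET2.

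Some genes were abundant in 1 library and nearly missing from the other. At 10 TPM or more in LongInsert and under 0.1 TPM in Regular there were 33 genes, and 18 genes showed the reverse. Of the 33, 5 had a symbol (CMC1, TMEM258, PSMD13, SETD1B and CBX1), and CBX1, a heterochromatin protein, had 10.6 and 0.0173 TPM. None of the 18 had a symbol.

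Ribosomal protein genes differed between the libraries by very different amounts. Their log2 ratios had quartiles of -0.33 and 2.79. A wide spread was not particular to them. Over all genes the quartiles were -0.74 and 2.41 from 10 to 100 TPM and -1.23 and 1.38 from 100 to 1000 TPM. Above 1000 TPM they were -1.39 and 0.60. A loss of short molecules from the library titled Regular may contribute. RPL38 and RPL39, with log2 ratios of 8.40 and 4.98, are among the smallest ribosomal proteins, but RPS3A, with a ratio of 6.94, is one of the larger ones and goes against it. All 3 members of the very long mRNA list were also lower in Regular, which such a loss alone would not produce. The size selection described goes with the title LongInsert, so that step would not act on Regular unless the titles were exchanged. Higher numbers were mostly given to smaller ribosomal proteins. The number in the name had a Spearman rho of 0.313 with the log2 ratio over 18 genes, at percentile 90.2 of 10000 shuffles. A loss of short molecules therefore stays open. Assignment of reads to different near-identical copies also stays open, since 0 of the 2 symbols with more than 1 listed gene had copies differing by 2-fold or more in opposite directions, and most copies were not analysed here.

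All 21 genes with a ZNF symbol and a mean of 1 TPM or more, most of them zinc finger proteins of low abundance, had more TPM in LongInsert, 14 of them by 2-fold or more. Their median log2 ratio was 1.78, and 282 of all 365 genes with a symbol were higher in LongInsert. ZNF839 had 9.25 TPM in LongInsert and 0.025 TPM in Regular, ZNF808 had 20.6 and 1.35 TPM, and ZNF706, the closest, had 69.6 and 50.4 TPM. Centring on genes with a mean of 10 TPM or more left a median of 1.19, with 19 of 21 genes still higher and a lower quartile of 0.26. It cannot exclude a difference in scaling for these genes, whose mean TPM had a median of 9.31. All genes from 1 to 10 TPM had a median log2 ratio of 1.45. Whether the lean of genes at that abundance may account for the higher ZNF values stays open. The median stood at percentile 88.0 of random lists of other genes matched on mean TPM, whose central 95% ran from 0.11 to 2.29, and at percentile 94.5 when the random lists were drawn from genes with a symbol only.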
